A study of Homo sapiens with 26 samples.

How the data were processed

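The series measured messenger RNA of human neurons grown in culture from neural stem cells (NSCs) of the established line XCL-1. Per the labels, an isogenic control was set beside cultures made to overexpress tau, the microtubule-binding protein encoded by MAPT, as Tau441, the longest isoform of the adult human brain, or as Tau11i. The series title ties the Tau11i form to translated sequence of retained intron 11. Per the labels' protocols, NSCs were seeded on coated plates, taken through neuronal induction medium, replated on day 6 and kept in a maturation medium until day 21 or day 55. RNA was enriched for poly-A tails and sequenced as paired ends on a NovaSeq instrument, per the labels' protocols.

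The 26 libraries fall into 9 groups by the genotype, line, day and batch that the labels give. Batch 1 holds 9 libraries of day 55, with 3 each of the control, Tau441 line 8 and Tau11i line 6. Batch 2 holds 9 more of day 55, with 3 each of the control, Tau441 line 20 and Tau11i line 25. Batch 3 holds the 8 libraries of day 21, with 2 controls, 3 of Tau441 line 8 and 3 of Tau11i line 6. At day 55 each tau line sits in 1 batch, so a difference between the lines of a construct is also a difference between batches, against each batch's own controls. The labels call the replicates biological replicates and say no more of them, so p-values reflect the spread between these samples. Whether equal replicate numbers pair the samples was read from the data, as the correlation of their deviations from the group means. Every pair of Tau11i with Tau441 in a batch passed 0.1 (0.316 to 0.693 in batch 1, 0.246 to 0.555 in batch 2, 0.680 to 0.957 in batch 3), and so did line 20 with its controls (0.124 to 0.214). These comparisons count as paired, and a fit with the number as a block is given beside them where it moved a result. The other comparisons with controls do not, with pairs down to -0.412 at day 55 and only 2 controls at day 21. Some unequal numbers passed 0.1 too, as line 25 replicate 1 with line 20 replicate 3 (0.384) and, at day 21, line 6 replicate 1 with line 8 replicate 2 (0.851). The pairing is thus a reading of the data that the labels do not give.

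The deposited table holds whole-number read counts per gene, not normalized. The submitters' processing notes name STAR 2.7.4a, HTSeq and DESeq2 and the genome build GRCh38, without a role or an order. The annotation release, the counting options and whether the library kit kept the strand are not given in the sources used here, so reads of a gene and of its antisense partner could not be separated. The table lists 62753 genes, of which 47344 had a count in any library and 42342 carry a symbol. By their identifiers, 58260 were placed in GENCODE release 29 on GRCh38, from which chromosomes, starts and ends were taken. Entries that name no gene, such as totals, numbered 0. A MAPT count made on the reference annotation adds reads of an introduced tau sequence to those of the cell's own gene.

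Total counts per library ran from 16185602 to 22044877 at day 21 and from 25902889 to 53369723 at day 55. For each library the share of mitochondrially encoded genes, the share of cytosolic ribosomal protein genes and the SD over genes of its log2 deviation from the mean of its batch were computed. A library stood apart where that SD passed 0.35, a threshold set after seeing the data. A chi-square comparison of all pairs within groups found no library deposited in duplicate, the smallest value per degree of freedom being 4.01.

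Counts were scaled with TMM factors, filtered with filterByExpr and tested with edgeR 4.0.16 (quasi-likelihood test) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. At day 55 all 18 libraries entered 1 fit with the batch as a term, testing Tau441 against control, Tau11i against control and Tau11i against Tau441. The same 3 comparisons were then made within batch 1 and within batch 2, which gives each line its own value, and at day 21 in the 8 libraries of batch 3. Interaction terms tested whether a construct's effect differed between its lines, and whether the effects of line 8 and line 6 differed between days. The controls of day 55 were compared with those of day 21, where day and batch are the same split.

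Gene lists numbered 45 and covered tau biology, neuron types, other cell types these cultures can hold, stress and degradation pathways, energy and lipid metabolism, immunity, matrix, RNA processing and RNA quality. Each list with at least 5 tested members was tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry. With observation weights the estimated correlation depends on the order of the design's columns, so it was also computed with the controls first, a check added after seeing the data. Median and mean fold changes were computed, and calls were counted over all genes tested and adjusted over the list alone. The lists, the groups, the fits and the first set of alternatives were fixed before the data were examined.

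Named genes followed a rule. For each genotype comparison it took MAPT, and the 10 largest positive and 10 most negative log2 fold changes among genes with an adjusted p under 0.05 and a mean log2 CPM (counts scaled to a common library total) of at least 1. At day 55 these also had to show the same sign in both batches. To these it added up to 4 members with the smallest p of every list that passed, held markers of other cell types or is described. For interactions and for the controls of the 2 days it took 5 per direction. Genes without a symbol, XIST and Y-linked genes were left out. A few genes outside the rule are given as chosen after their values were seen.

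Alternatives chosen beforehand were size factors of the RLE kind or none, no filter on low counts, DESeq2 1.42.0, the replicate number as a block, no batch term, 1 mean per group, all 26 libraries in 1 fit, and leaving out each library in turn. Added after seeing the data were offsets for the GC content and transcript length trend of each library, a fit without the libraries standing apart, limma-voom with sample quality weights, and for paired comparisons the block and the offsets in 1 fit. The trend offsets used splines with 5 degrees of freedom on the GC content and length of each gene's longest GENCODE transcript. Of the genes tested at day 55, 95% had a GC and length value. Overlap between comparisons that share controls was set beside 20 simulations of unchanged groups against those controls. Counts of calls were set beside 100 drawn regroupings of the libraries, or all 10 where no more exist, and for paired comparisons beside all splits that part every pair.

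The scripts were tested on simulated data with 200 known changes. At day 55 Tau441 against control (21876 genes) called 34.3% of genes changed by 0.5 (log2), 97.0% by 1 and all 66 by 2. Unchanged genes gave 7 calls. At day 21 the same comparison (20018 genes) called 0 of 67 genes changed by 1 and 16.7% of those changed by 2. Of genes changed by 1 at day 55, line 8 alone (20754 genes) called 53.7% and line 6 alone (20777 genes) 55.2%. These rates are for simulated spread, and real changes this large may be missed more often. A simulated GC trend with no changed gene gave 5328 calls among 21847 genes, and 0 after the offsets.

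Folds against a group with 0 counts in all libraries are lower bounds set against 3 counts over the group, which cover counting error only. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The levels of XIST and of Y-linked genes were not used here. Some genes are not reported here.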

Results

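Poly-A RNA was counted in 26 cultures of neurons derived from NSCs of the line XCL-1. At day 55 there were 6 isogenic control, 6 Tau441 and 6 Tau11i libraries, each set of 6 made of 3 libraries in batch 1 and 3 in batch 2. At day 21 there were 2 control, 3 Tau441 and 3 Tau11i libraries in batch 3. Library totals were 16185602 to 22044877 counts at day 21 and 25902889 to 53369723 at day 55. The design asks what overexpressed tau changes in these neurons, whether the Tau11i form differs from Tau441, whether the lines of a construct act alike and whether an effect at day 55 is already there at day 21.

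MAPT, the tau gene on chromosome 17 (ENSG00000186868, 45894382 to 46028334 on the plus strand of GRCh38), checks the labels. In batch 1 of day 55 it stood at 769 ± 78.7 CPM in the controls, 1738 ± 193 in Tau441 line 8 and 1652 ± 82.9 in Tau11i line 6 (mean ± SD, n = 3 each). In batch 2 the controls held 631 ± 46.1 CPM, Tau441 line 20 held 808 ± 23.9 and Tau11i line 25 held 958 ± 7.92 (n = 3 each). MAPT rose in Tau441 over both batches by a log2 fold change of 0.78 (SE 0.12), adjusted p = 0.0208, and in Tau11i by 0.84 (SE 0.12), adjusted p = 0.00596. Within batches it rose in line 8 (1.19 (SE 0.15)) and line 6 (1.10 (SE 0.15)), while line 20 had 0.39 (SE 0.08) with adjusted p = 0.203 and line 25 had 0.62 (SE 0.08) with adjusted p = 0.0775. Between Tau11i and Tau441 the test over both batches did not pass (0.05 (SE 0.12), adjusted p = 0.804). MAPT differed by -0.08 in batch 1 and 0.23 in batch 2, where the line 25 libraries (951 to 966 CPM) all lay above those of line 20 (784 to 831). At day 21 the 2 controls held 1483 and 1377 CPM, and neither Tau441 line 8 at 1829 ± 404 nor Tau11i line 6 at 1698 ± 220.3 CPM (n = 3 each) passed the test, with log2 fold changes of 0.40 (SE 0.22) and 0.28 (SE 0.22). Of these tau libraries line 8 replicate 3 at 1386 and line 6 replicate 3 at 1445 CPM lay between the 2 controls. A count made on the reference gene sums transgene and endogenous transcripts. The rise in Tau441 missed the threshold without batch 1 control replicate 1 (0.72), replicate 2 (0.70) or replicate 3 (0.76), line 20 replicate 1 (0.82) or replicate 2 (0.81), or line 8 replicate 1 (0.77), replicate 2 (0.77) or replicate 3 (0.69). In line 8 alone it did so without batch 1 control replicate 1 (1.19) or replicate 2 (1.13) or line 8 replicate 3 (1.07). In line 6 alone it did so without control replicate 1 (1.08).

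**Figure D1:**
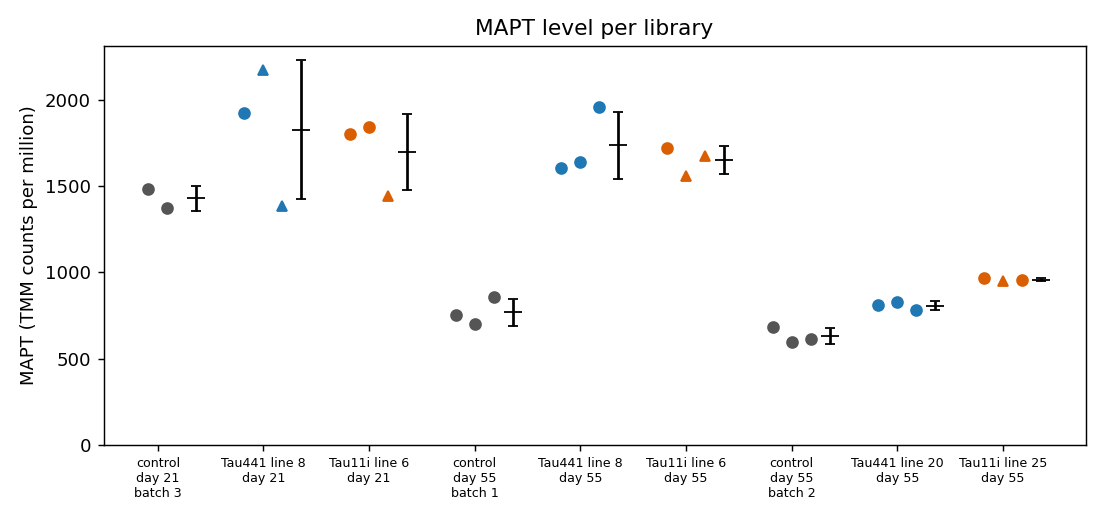
MAPT level in CPM (y axis, linear) of each library in the 9 groups (x axis), with bars for the mean ± SD and triangles for libraries standing apart from their batch. Batch 1 controls average 769 and batch 2 controls 631, against 1738 in Tau441 line 8, 1652 in Tau11i line 6, 958 in Tau11i line 25 and 808 in Tau441 line 20, while the day 21 controls lie at 1483 and 1377.

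Of the 18 tau libraries 6 stood apart from the mean of their batch, and of the 8 controls 0, with unusual shares of mitochondrial or ribosomal protein transcripts at day 55 and unusual GC trends at day 21. At day 55 these were Tau11i line 6 replicates 2 and 3 and Tau11i line 25 replicate 2, with SDs of 0.390, 0.601 and 0.443 on the log2 scale. Mitochondrially encoded genes took 10.6% of counts in each of these line 6 libraries, against 4.27% to 6.63% in the other day 55 libraries, with 5.06% in line 25 replicate 2. Genes of the cytosolic ribosome took 3% and 3.27% in those of line 6 and 3.58% in line 25 replicate 2, against 1.77% to 2.39% in the others. In the same order these libraries held counts for 28587, 28708 and 29156 genes, against 30436 to 32588 in the other day 55 libraries. Their log2 levels moved with transcript length by -0.184, -0.212 and -0.251 per doubling, against -0.106 to 0.153 in the others, so longer transcripts were lower. At day 21 Tau11i line 6 replicate 3 (0.638) and Tau441 line 8 replicates 2 (0.598) and 3 (0.638) stood apart. Their log2 levels moved with GC content by -0.635, 0.587 and -0.623 per 10 percentage points, against 0.00479 to 0.259 in the other day 21 libraries. Comparisons with tau libraries are also given without those that stand apart, an alternative chosen after seeing the data. That leaves 1 library of line 6 at day 55 and 1 of line 8 at day 21, whose spread is then taken from the other groups.

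**Figure D2:**
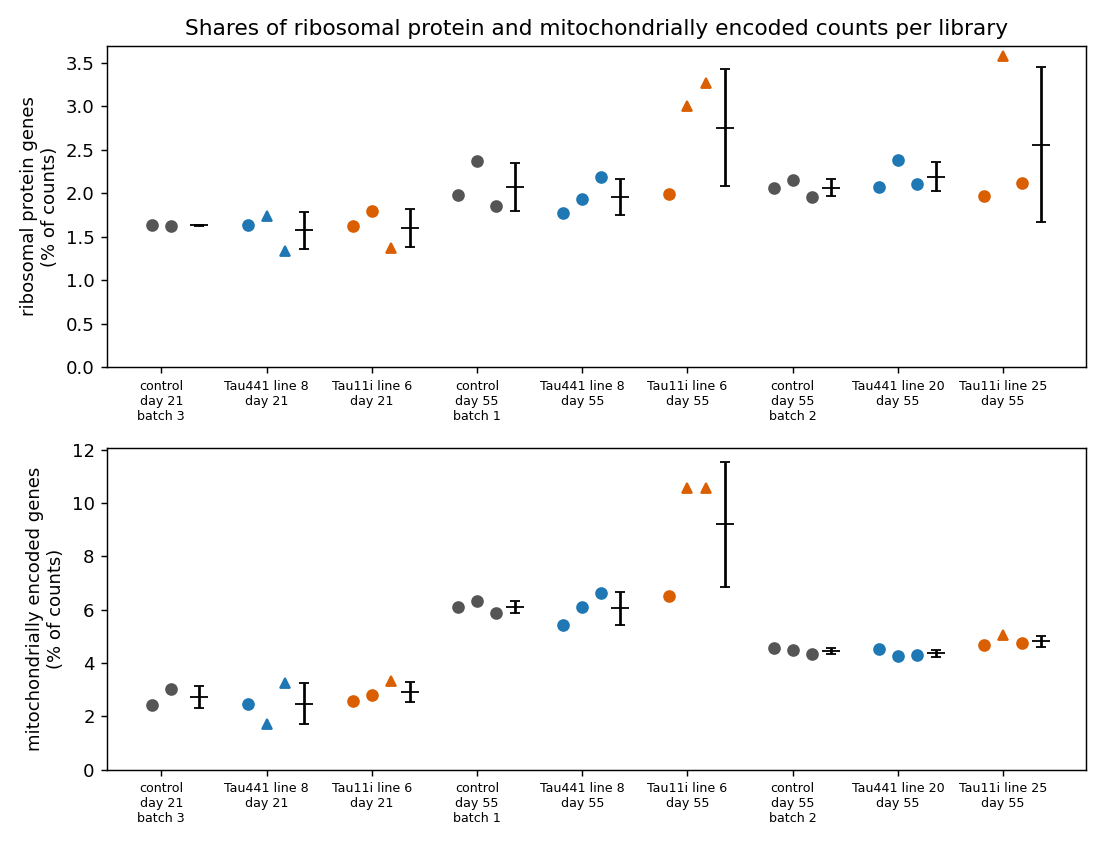
Share of counts from mitochondrially encoded genes and from cytosolic ribosomal protein genes, in percent (y axes), for each library by group (x axis), with bars for the mean ± SD and triangles for libraries standing apart. The mitochondrial share is 10.6% in 2 libraries of Tau11i line 6 and 4.27% to 6.63% in the other libraries of day 55.

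At day 55 general neuronal genes were lower as a group in the Tau441 cultures than in the isogenic controls by camera's test. Pan-neuronal genes fell in that test, with a median log2 fold change of -0.26, 17 of 20 genes lower and a camera adjusted p of 1.82e-08, with n = 6 against 6. With an estimated correlation the adjusted p was 0.0577, or 0.046 with the controls as the first columns of the design. Their medians were -0.20 in line 8 and -0.31 in line 20. STMN2, which regulates microtubules in growing axons, had -0.40 (SE 0.10), the neurofilament genes INA and NEFH had -0.36 (SE 0.09) and -0.45 (SE 0.12), and CHGB of secretory granules had -0.45 (SE 0.13). None of the 20 passed over all genes tested, and 8 were lower adjusted over the list alone. GABAergic markers fell in it as well (median -0.20, 10 of 12 lower, adjusted p = 0.00075, and 0.0577 or 0.046 with an estimated correlation in these 2 column orders), with medians of -0.27 in line 8 and -0.47 in line 20. The neuropeptide genes NPY and SST had -0.82 (SE 0.20) and -0.80 (SE 0.27), and 4 of the 12 were lower adjusted over the list alone. Beside both falls, astrocyte markers rose in camera's test (median 0.14, 13 of 18 higher, adjusted p = 0.00919), with an adjusted p = 0.533 with an estimated correlation, FGFR3 at 0.45 (SE 0.10) and CHI3L1 at 0.74 (SE 0.19). Without the libraries standing apart, all of them Tau11i, the Tau441 medians were -0.26 for pan-neuronal, -0.21 for GABAergic and 0.12 for astrocyte genes.

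Genes of cholesterol synthesis were lower in Tau441 (median -0.23, 20 of 24 lower, camera adjusted p = 8.99e-08), with an adjusted p = 0.0761 with an estimated correlation and 7 genes lower adjusted over the list alone. IDI1 and SQLE, enzymes of the mevalonate and squalene steps, had -0.47 (SE 0.13) and -0.38 (SE 0.12), and INSIG1, which restrains the pathway's transcription factor, had -0.50 (SE 0.14). Presynaptic genes fell in camera's test (median -0.21, 22 of 26 lower, adjusted p = 2.2e-05, and 0.0761 with an estimated correlation), among them SNAP25 of vesicle fusion (-0.34 (SE 0.10)) and CPLX2 (-0.34 (SE 0.12)). Cytosolic heat shock genes (-0.16, 18 of 20 lower), proteasome subunits (-0.13, 28 of 30), genes of the integrated stress response (-0.12, 18 of 21) and kinases and phosphatases that act on tau (-0.07, 19 of 25) had small negative medians. These 4 lists passed camera with adjusted p of 0.000599, 0.00123, 0.00364 and 0.0204, and had adjusted p of 0.242, 0.662, 0.331 and 0.252 with an estimated correlation. DNAJA1 and HSPA8, chaperones of the cytosol, had -0.31 (SE 0.11) and -0.23 (SE 0.08), PSMC1 had -0.18 (SE 0.09), and CDK5R2, an activator of the tau kinase CDK5, had -0.32 (SE 0.11). Immediate early genes (median -0.17) and genes of the oxidative stress response under NRF2 (median -0.13) passed camera as lower at adjusted p = 0.0365 each, with adjusted p of 0.386 and 0.662 with an estimated correlation, and neither passed with GC and length offsets. Without the libraries standing apart the medians were -0.24 for cholesterol synthesis, -0.22 for presynaptic, -0.16 for heat shock, -0.14 for proteasome and -0.13 for integrated stress response genes. They were -0.08 for tau kinases and phosphatases, -0.18 for immediate early and -0.14 for NRF2 genes. In all, 11 of 43 lists passed camera in this comparison, and with an estimated correlation 0 did, or 2, pan-neuronal and GABAergic genes, with the controls as the first columns. Proliferation genes had a median of 0.09 and a mean of 0.03 while camera's direction was down (adjusted p = 0.978).

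Among single genes, 9 of 22333 tested passed, 3 higher and 6 lower in Tau441. Beside MAPT, SLN (sarcolipin, a small regulator of the calcium pump; ENSG00000170290, chromosome 11, 107707378 to 107719693) rose by 1.55 (SE 0.27) with adjusted p = 0.0399, with 2.005 in line 8 and 1.13 in line 20. EMX2OS, antisense to the forebrain gene EMX2 and chosen after its value was seen, rose by 4.41 (SE 0.80), with 4.57 in line 8 and no test in line 20, since it missed the count filter in batch 2. Its reads could not be separated from those of EMX2, which had 2.29 (SE 0.86). TAC1, the precursor of substance P (ENSG00000006128, chromosome 7, 97731908 to 97740472), fell with -1.38 (SE 0.24) (-1.93 and -0.71 in the 2 lines), and carboxypeptidase M, whose symbol is CPM, with -0.94 (SE 0.16). PPP2R2C, a regulatory subunit of the phosphatase PP2A (ENSG00000074211, chromosome 4, 6320578 to 6563600), fell with -0.77 (SE 0.12) (-0.98 and -0.54). The matrix protease gene MMP10 (-0.76 (SE 0.14)), the phosphatase gene DUSP5 (-0.69 (SE 0.13)) and GPNMB (-0.69 (SE 0.11)) fell as well. At an unadjusted p under 0.05 there were 1937 genes, and without the libraries standing apart 208 genes passed, holding all 9. The count was 130 with DESeq2, 254 without the count filter, 143 with GC and length offsets, 115 with voom weights, 34 with 1 mean per group, 4 in the fit of all 26 libraries and 0 without a batch term. With 1 library left out there were 0 calls without batch 1 control replicate 2 or 3, line 20 replicate 1 or 2 or any replicate of line 8, 1 without batch 1 control replicate 1. There were 3 without line 20 replicate 3 or line 6 replicate 2, 4 without batch 2 control replicate 1, 26 without batch 2 control replicate 2 and 32 without line 6 replicate 3.

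In the Tau11i cultures of day 55, transcripts for cytosolic ribosomal proteins and those encoded by the mitochondrial genome were higher than in the controls as groups. Ribosomal protein genes rose in camera's test (median 0.47, 44 of 44 higher, adjusted p = 2.06e-14; n = 6 against 6), with an adjusted p = 0.746 with an estimated correlation. RPLP0 had 0.60 (SE 0.17) and RPS27 0.70 (SE 0.21), and 37 of the 44 were higher adjusted over the list alone, 0 over all genes tested. Mitochondrially encoded genes did so too (median 0.49, 13 of 13 higher, adjusted p = 5.13e-06, and 0.746 with an estimated correlation), with MT-ATP6 at 0.64 (SE 0.17) and MT-CO3 at 0.50 (SE 0.14), and 10 higher adjusted over the list alone. The ribosomal medians were 0.56 in line 6 and 0.36 in line 25, the mitochondrial ones 0.92 and 0.09. Of the 3 libraries standing apart all had high ribosomal shares and the line 6 ones high mitochondrial shares, and without the 3 the medians were -0.03 for ribosomal (adjusted p = 0.219) and 0.08 for mitochondrial genes (adjusted p = 0.00826).

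Further lists that passed camera for Tau11i also moved with those 3 libraries. Nuclear genes of oxidative phosphorylation (median 0.21, 34 of 38 higher, adjusted p = 0.000546) and glycolysis genes (median 0.19, 16 of 19 higher, adjusted p = 0.00763) had an adjusted p = 0.746 with an estimated correlation, and medians of -0.11 and -0.05 without those libraries. Astrocyte markers (median 0.30, 13 of 18 higher, adjusted p = 0.0202, and 0.746 with an estimated correlation) had 0.04 without them. Of the astrocyte genes 1 passed over all genes tested and 5 adjusted over the list alone, with FGFR3, a growth factor receptor, at 0.56 (SE 0.10), S100B at 0.61 (SE 0.15), CLU at 0.54 (SE 0.17) and AGT at 0.87 (SE 0.26). Voltage-gated ion channels (median -0.23, 22 of 26 lower, adjusted p = 0.00365), axon guidance genes (-0.21, 24 of 32, adjusted p = 0.0153) and postsynaptic genes (-0.29, 23 of 30, adjusted p = 0.0196) were lower, all with an adjusted p = 0.746 with an estimated correlation. Their medians were 0.01, 0.06 and -0.02 without those libraries. CACNA2D1 had -0.57 (SE 0.18) and UNC5D -0.76 (SE 0.21), while GRIA3, an AMPA receptor subunit, had 1.25 (SE 0.30) and was the 1 postsynaptic gene to pass adjusted over the list alone. In all, 8 of 43 lists passed camera and 0 with an estimated correlation, and the 3 lower lists and glycolysis did not pass with GC and length offsets. With those offsets 10 lists passed, only 4 of them among the 8 and in the same direction. Pan-neuronal genes had a median of -0.10 (14 of 20 lower, adjusted p = 0.0829), and -0.12 without the 3 libraries.

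Among single genes 21 of 22333 passed for Tau11i, 7 higher and 14 lower. BNC2, a zinc finger transcription factor (ENSG00000173068, chromosome 9, 16409503 to 16870843), fell with -1.53 (SE 0.21) and adjusted p = 0.00596, and the transcription factor ETS1 with -1.22 (SE 0.22). TMEM200A (-1.11), carboxypeptidase M (-1.11), AFF2 (-1.03), the potassium-dependent sodium-calcium exchanger SLC24A2 (-1.03), the splicing regulator RBM20 (-0.99), the cell cycle kinase WEE1 (-0.93), B3GALNT1 (-0.78) and the collagen gene COL5A2 (-0.77) fell, with SEs of 0.11 to 0.22. STUM (0.86 (SE 0.17)), the carbonic anhydrase CA14 (0.74 (SE 0.12)), LRRN2 (0.72 (SE 0.14)) and FGFR3 rose with MAPT. At an unadjusted p under 0.05 there were 5352 genes, and without the 3 libraries standing apart 1 passed, MAPT at 0.85. DESeq2 called 810 genes, and the count was 2294 without the count filter, 254 with 1 mean per group, 113 with GC and length offsets, 5 with voom weights and 0 without a batch term. Leaving out 1 library gave 6, 11 and 7 calls without batch 1 control replicates 1, 2 and 3, and 12 and 36 without batch 2 control replicates 1 and 2. It gave 111, 12 and 65 without line 25 replicates 1, 2 and 3, and 71, 7 and 12 without line 6 replicates 1, 2 and 3.

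Tau441 and Tau11i shared 4 called genes at day 55, with MAPT and EMX2OS higher and carboxypeptidase M and PPP2R2C lower in both. PPP2R2C had -0.77 (SE 0.12) and -0.74 (SE 0.12) and EMX2OS 4.41 (SE 0.80) and 4.31 (SE 0.79), the last 2 Tau11i values chosen after they were seen. EMX2OS was tested within lines 8 and 6 only, against the same 3 batch 1 controls, and missed the count filter in batch 2. Both comparisons used the same 6 controls, and 20 simulations of unchanged groups against those controls shared 0 genes. Lists of these lengths drawn independently would share 0.00094 genes upward and 0.00376 downward. The simulated genes varied independently and held no difference between lines or single libraries. Neither value therefore shows what such differences would share, and MAPT is shared by design. Over all genes the fold changes correlated at r = 0.300 against 0.490 in the simulations, genes not being independent replicates, and their covariance was 0.0350 against 0.0340 simulated. With the controls split so that the constructs shared none, r was -0.0170 and 0.136 in the 2 arrangements, and Tau441 then called 0 genes, so no call could be shared. The 4 became 36 with DESeq2, 75 without the count filter, 23 with GC and length offsets, 11 with 1 mean per group, 1 without the libraries standing apart, 1 in the fit of all 26 libraries and 0 without a batch term. They became 0 without any of the batch 1 controls, any line 8 library or line 20 replicate 1 or 2, 1 without line 6 replicate 2, 2 without batch 2 control replicate 1 or line 20 replicate 3, and 9 without batch 2 control replicate 2.

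Set directly against Tau441 at day 55, the Tau11i cultures had higher medians for genes of protein synthesis, respiration and degradation. Ribosomal protein genes (median 0.44, 43 of 44 higher, camera adjusted p = 6.21e-13), mitochondrially encoded genes (0.54, 11 of 13, adjusted p = 9.83e-06), nuclear genes of oxidative phosphorylation (0.32, 32 of 38, adjusted p = 7.05e-06) and proteasome subunits (0.23, 26 of 30, adjusted p = 0.000176) rose in camera's test (n = 6 against 6). Their adjusted p was 0.597 each with an estimated correlation, and 35, 10, 18 and 12 of their genes were higher adjusted over the list alone. RPL19 had 0.59 (SE 0.17), MT-CO3 0.60 (SE 0.14), ATP5MC1 0.54 (SE 0.15) and PSMB3 0.61 (SE 0.16). The same 3 Tau11i libraries moved these groups, whose medians without them were -0.04, 0.13, -0.01 and 0.02. Glycolysis (0.22), cholesterol synthesis (0.15), NRF2 (0.28), tau kinase and phosphatase (0.15) and lysosome genes (0.11) also passed as higher, with adjusted p of 0.000553, 0.000994, 0.0221, 0.0321 and 0.0382, and 0.597 each with an estimated correlation, and lysosome genes did not pass with GC and length offsets. CDK5 had 0.57 (SE 0.16) and its activator CDK5R2 0.48 (SE 0.11), DHCR7 of cholesterol synthesis 0.51 (SE 0.14), and the lysosomal protease CTSD 0.63 (SE 0.20), which turned to -0.01 without those libraries. The 5 medians were then 0.05, 0.15, 0.01, 0.05 and 0.01. Ion channels (-0.18, 22 of 26 lower, adjusted p = 0.0185) and axon guidance genes (-0.18, 26 of 32 lower, adjusted p = 0.011) passed as lower, with adjusted p = 0.687 with an estimated correlation, 0.03 and 0.03 without the libraries standing apart and no pass with GC and length offsets. That makes 11 of 43 lists.

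Between Tau11i and Tau441 9 of 22333 genes passed, 3 higher and 6 lower. The transcription factor genes OTP (1.11 (SE 0.16); ENSG00000171540, chromosome 5, 77628712 to 77639688) and NHLH1 (1.01 (SE 0.14)) of developing neurons and TMEM97 (0.55 (SE 0.10)) were higher in Tau11i. AHNAK, a large scaffold protein gene (-1.50 (SE 0.24)), BNC2 (-1.34 (SE 0.21)), the long noncoding RNA PURPL (-1.27 (SE 0.23)), SYNE3 (-0.99 (SE 0.16)), the decoy death receptor TNFRSF10D (-0.96 (SE 0.14)) and IL1RAP (-0.65 (SE 0.11)) were lower. At an unadjusted p under 0.05 there were 5935 genes, and 0 passed without the libraries standing apart. These libraries count as paired by the rule read from the data. With the replicate number as a block 308 genes passed, holding all 9, and 1066 with GC and length offsets in the same fit. MT-CO3 at 0.59 (adjusted p = 0.0437) and CDK5R2 at 0.48 (adjusted p = 0.0370) passed with the block. The count was 2051 with DESeq2, 3140 without the count filter, 232 with 1 mean per group, 159 with GC and length offsets, 4 with voom weights and 0 without a batch term. Leaving out 1 library gave 2207, 3 and 2335 calls without line 25 replicates 1, 2 and 3. It gave 2776 and 4 without line 6 replicates 1 and 2, 4 and 5 without line 20 replicates 2 and 3, and 3 without line 8 replicate 1.

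**Figure D3:**
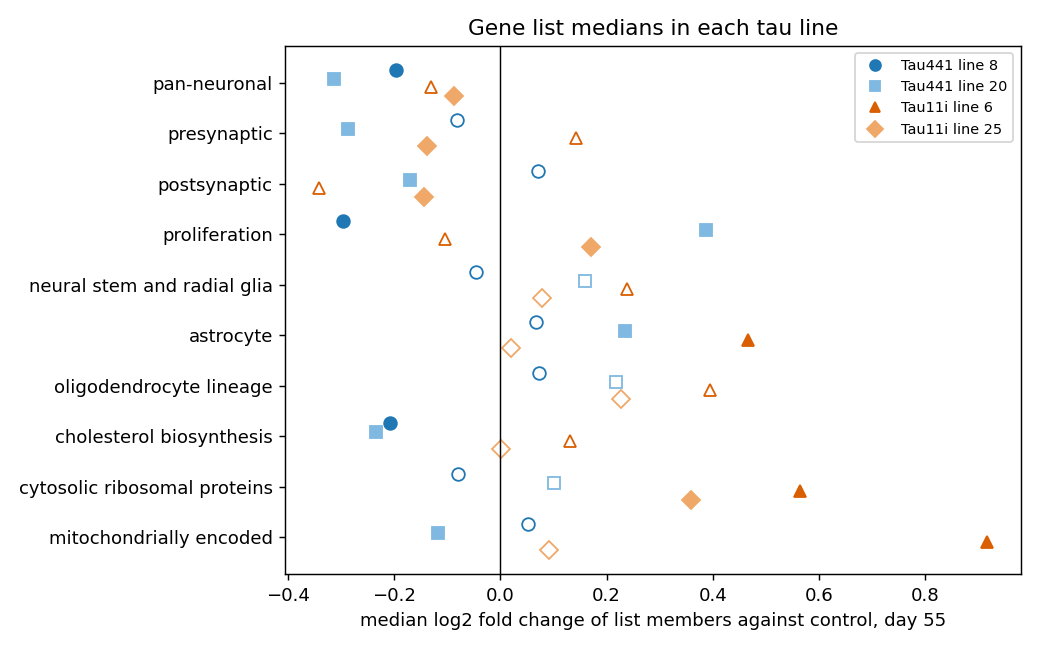
Median log2 fold change (x axis) of the members of selected gene lists (y axis) in each of the 4 tau lines against the controls of its batch at day 55. Filled points pass camera at an adjusted p under 0.05. Ribosomal protein genes have positive medians in both Tau11i lines, and pan-neuronal genes have negative medians in both Tau441 lines.

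Line by line, Tau441 line 8 carried a small set of large changes. Against batch 1 controls (n = 3 against 3) 10 of 21380 genes passed, 4 higher and 6 lower. EFEMP1, a matrix protein gene, rose by 4.08, TWIST1, a mesenchymal transcription factor gene, by 2.28 and EMX2OS by 4.57, all beside MAPT. FIBIN (-3.76), EMC10 of the membrane protein insertion complex (-3.25), MAP1LC3A of autophagosomes (-2.70), the metallothionein MT1G (-2.62), the dynein light chain DYNLT3 (-2.35) and TAC1 (-1.93) fell. Line 6, against the same controls, had values near those of line 8 for EFEMP1 (4.03), EMX2OS (5.21), TWIST1 (2.41), TAC1 (-1.66) and DYNLT3 (-1.62). It had -1.89 for FIBIN, -1.15 for MAP1LC3A, -0.64 for MT1G and -0.18 for EMC10. Line 20 had 0.31 for EFEMP1, -1.30 for TWIST1, 0.09 for FIBIN, -0.18 for EMC10, -0.01 for MAP1LC3A, 0.01 for DYNLT3, -0.85 for MT1G and -0.71 for TAC1. Of lists, proliferation genes (median -0.30, 23 of 25 lower, adjusted p = 4.49e-06), cholesterol synthesis (-0.21, 20 of 24), pan-neuronal (-0.20), heat shock (-0.21) and integrated stress response genes (-0.22) fell in camera's test, all with an adjusted p = 0.523 with an estimated correlation. Nuclear RNAs kept as signs of RNA quality rose as a list (median 0.26, 9 of 12 higher, adjusted p = 0.0297, and 0.523 with an estimated correlation), with MALAT1 at 3.72 (SE 0.91) and NEAT1 at 0.97 (SE 0.30), and did not pass with GC and length offsets. There were 1457 genes at an unadjusted p under 0.05. The count was 81 with DESeq2, 176 without the count filter, 42 with GC and length offsets and 58, holding all 10, without the libraries standing apart. It was 2 without batch 1 control replicate 2, 3 without line 8 replicate 3, 44 without line 6 replicate 1 and 22 without line 6 replicate 3.

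**Figure D4:**
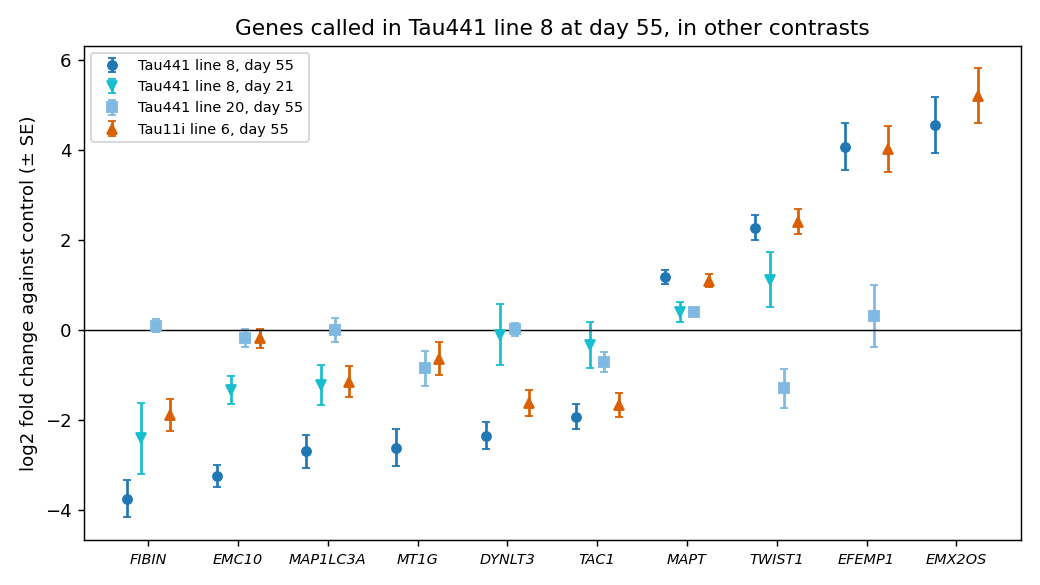
Log2 fold change against control (y axis) of the genes called in Tau441 line 8 at day 55 (x axis), in line 8 at day 55, line 8 at day 21, line 20 at day 55 and Tau11i line 6 at day 55, with bars for 1 SE. FIBIN lies at -3.76 in line 8 at day 55, -2.42 at day 21, 0.09 in line 20 and -1.89 in line 6.

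Tau441 line 20 had lower neuronal and synaptic lists and higher lists of dividing and glial cells against batch 2 controls (n = 3 against 3). Pan-neuronal genes (median -0.31, 19 of 20 lower, adjusted p = 6.43e-11, and 0.116 with an estimated correlation) and presynaptic genes (-0.29, 24 of 26 lower, adjusted p = 6.43e-11, and 0.116) fell in camera's test, 12 and 11 of them adjusted over the list alone. Beside these, proliferation genes (median 0.39, 21 of 25 higher, adjusted p = 2.72e-09, and 0.271 with an estimated correlation) and astrocyte markers (0.23, 14 of 18 higher, adjusted p = 0.000137, and 0.38) rose. GABAergic markers (-0.47, adjusted p = 3.17e-05, and 0.116 with an estimated correlation) and cholesterol synthesis (-0.23, 22 of 24 lower, adjusted p = 1.15e-08, and 0.271) fell. In all, 17 lists passed camera in line 20 and 0 with an estimated correlation. No single gene of 22663 passed with edgeR, against 2093 at an unadjusted p under 0.05, 365 with DESeq2 and 392 without the count filter. With the replicate number as a block the count stayed at 0, and with GC and length offsets in the same fit 560 passed, MAPT among them at 0.41. Without line 25 replicate 2, a Tau11i library that stands apart, 1868 passed, and without batch 2 control replicate 2 the count was 145. MAPT passed without line 25 replicate 2, at 0.39.

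Tau11i line 6 differed from batch 1 controls in 102 of 21380 genes, 73 higher and 29 lower (n = 3 against 3). Of 101 of these, 33 of 87 tested kept their sign at day 21 and 57 of 97 in line 25. SLITRK2 (3.59 (SE 0.32)), TWIST1 (2.41), the AMPA receptor partner SHISA9 (2.35), GRIA3 (2.16) and the inhibitory transporter SLC32A1 (2.02) rose. So did CDH13 (1.83) and the progenitor genes HES5 (1.65) and SOX3 (1.60). PCDHGB9P (6.52), a pseudogene that can share reads with its protocadherin cluster, is uncertain. GLP1R (-2.59), TPH2 of serotonin synthesis (-2.56), FIBIN (-1.89) and KLF8 (-1.66) fell. Astrocyte genes rose as a list (median 0.47, adjusted p = 0.000831), with ALDOC at 1.78 (SE 0.21) and AGT at 1.37 (SE 0.25) called over all genes and 10 of 18 adjusted over the list alone. Mitochondrial (0.92), ribosomal (0.56), glycolysis (0.43) and oxidative phosphorylation genes (0.27) passed as higher too, all 5 lists with adjusted p = 0.909 with an estimated correlation. With GC and length offsets 10 lists passed camera, 5 of them passing in the same direction without the offsets. Without replicates 2 and 3, which stand apart, the medians of the 5 lists named here were 0.33, 0.15, -0.01, 0.10 and -0.12, with 1 line 6 library left. Unadjusted, 5637 genes had p under 0.05. DESeq2 called 2241, the fit without the count filter 2381 and GC and length offsets 284. The count became 23, 29 and 20 without batch 1 control replicates 1, 2 and 3, and 6905, 24 and 59 without line 6 replicates 1, 2 and 3.

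In Tau11i line 25, set against batch 2 controls (n = 3 against 3), lists of protein synthesis and division rose and lists of membrane excitability fell in camera's test. Ribosomal protein genes (median 0.36, 44 of 44 higher, adjusted p = 1.09e-09) and proliferation genes (0.17, 21 of 25 higher, adjusted p = 0.00232) rose, with adjusted p of 0.693 and 0.693 with an estimated correlation. Ion channels (-0.28, 23 of 25 lower), postsynaptic (-0.14, 27 of 29) and antigen presentation genes (-0.26, 10 of 13) fell, at adjusted p of 2.71e-07, 1.66e-05 and 0.00214, and 0.503, 0.503 and 0.503 with an estimated correlation. Without replicate 2, which stands apart, these 5 medians were -0.01, 0.10, -0.12, -0.04 and -0.31, and 85 genes passed, MAPT among them at 0.63. With all libraries edgeR called 0 of 22663 genes, with 1420 at an unadjusted p under 0.05, 81 with DESeq2, 198 without the count filter and 7 with GC and length offsets. Without batch 2 control replicate 2 the count was 1.

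Between the constructs within a batch, line 6 exceeded line 8 in 36 genes and fell below it in 5 of 21380. EMC10 (3.07 (SE 0.24)), SLITRK2 (2.17 (SE 0.30)), the astrocyte genes ALDOC (2.23) and CST3 (1.80), the Notch genes MFNG (1.97), HEY2 (1.84) and HES5 (1.77) and the glial progenitor gene OLIG1 (1.70) were higher in line 6. COL8A1 (-1.60), BNC2 (-1.56), SHOX2 (-1.25) and PMP2 (-1.24) were lower. With the libraries standing apart left out and 1 line 6 library left, 7 genes passed, and 5271 had an unadjusted p under 0.05. With the replicate number as a block 1923 passed, holding all 41, and 1891 with GC and length offsets in the same fit. DESeq2 called 1636, the fit without the count filter 2478 and GC and length offsets 203. The count was 6954 and 3 without line 6 replicates 1 and 2, and 5, 18 and 24 without line 8 replicates 1, 2 and 3. Line 25 differed from line 20 in 10 of 22663 genes, with TCEAL7 higher (0.84 (SE 0.12)) and the small heat shock protein HSPB8 (-2.10 (SE 0.23)), PURPL (-1.81), the elastic fibre gene FBLN5 (-1.67), SLFN12 (-1.61), the sodium channel subunit SCN4B (-1.24) and COL5A2 (-0.82) among the 9 lower. Extracellular matrix genes (median -0.24, adjusted p = 2.09e-05) and antigen presentation genes (-0.30, 12 of 13 lower, adjusted p = 6.54e-06) were lower in line 25 and pan-neuronal genes higher (0.24, adjusted p = 4.82e-05), with adjusted p of 0.27, 0.103 and 0.282 with an estimated correlation. Their medians were -0.13, -0.47 and 0.21 without line 25 replicate 2, which stands apart, while astrocyte genes beside them had -0.32 (0.385 with an estimated correlation) and -0.36. With the replicate number as a block 5 of the 10 passed, TCEAL7, SLFN12 and COL5A2 not among them, and 78 with GC and length offsets in the same fit, holding all 10. There were 2163 genes at an unadjusted p under 0.05, 238 with DESeq2, 384 without the count filter and 59 with GC and length offsets. The count was 434 without line 25 replicate 2, 2 without batch 2 control replicate 1 and 0 without line 25 replicate 1 or 3 or any line 20 library.

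The lines of a construct were then compared directly. With edgeR lines 20 and 25 had 0 calls each (2093 and 1420 genes at an unadjusted p under 0.05, 365 and 81 with DESeq2), so 0 genes could pass in both lines of a construct. Genes called in the same direction in both Tau441 lines and in both Tau11i lines numbered 4 and 13 with DESeq2, 12 and 53 without the count filter, 11 and 1 without the libraries standing apart and, without line 25 replicate 2 alone, 2 and 3. Genes called in opposite directions numbered 2 and 8 with DESeq2, 3 and 9 without the count filter, 3 and 2 without the libraries standing apart and 0 and 3 without line 25 replicate 2 alone. Over 20761 genes the fold changes of lines 8 and 20 correlated at r = 0.109 and those of lines 6 and 25 at r = 0.212, each pair having its own controls, with genes not independent replicates. Without the libraries standing apart the second was 0.00454, and without line 25 replicate 2 alone it was -0.0790. The interaction test called 11 of 23561 genes for Tau441, with 1613 at an unadjusted p under 0.05, WNT7B (2.44) and BHLHE22 (1.78) more positive and FIBIN (-3.86) and EMC10 (-3.08) more negative in line 8 than in line 20. It called 50 for Tau11i, with 3175 at an unadjusted p under 0.05, SLITRK2 (5.02), SHISA9 (3.50) and HSPB8 (2.85) higher and KLF8 (-2.00) and GATA3 (-1.78) lower in line 6 than in line 25. Leaving out the libraries standing apart gave 80 for Tau441, holding all 11, and 44 for Tau11i, holding 31 of the 50. The first count was 6 without batch 1 control replicate 1 or 3, 5, 38 and 6 without batch 2 control replicates 1, 2 and 3, and 17 without line 25 replicate 2. It was also 23 and 20 without line 6 replicates 1 and 3, and 6 without line 20 replicate 1 or 3 or line 8 replicate 1 or 2. The second was 29, 32 and 26 without the batch 1 controls, 20 and 30 without batch 2 control replicates 1 and 3. Further, it was 27, 109 and 21 without the line 25 libraries, and 1767 and 19 without line 6 replicates 1 and 2.

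At day 21 no gene of 20562 passed with edgeR in Tau441 line 8 or Tau11i line 6 against the 2 controls, or between lines. Lists of inhibitory neurons, progenitors and antigen presentation passed camera in both, but against the same controls, so not independently. GABAergic markers fell in camera's test in Tau441 (median -0.45, 7 of 9 lower, adjusted p = 0.000538) and in Tau11i (-0.17, 6 of 9 lower, adjusted p = 0.00471), with adjusted p of 0.225 and 0.274 with an estimated correlation. Neural stem genes rose in camera's test in Tau11i (median 0.27, 17 of 20 higher, adjusted p = 0.0136, and 0.814 with an estimated correlation), with VIM at 0.66 (SE 0.19) and SOX3 at 0.85 (SE 0.26), and in Tau441 (0.13, adjusted p = 0.0239, and 0.769). Antigen presentation genes fell in it in both (-0.27 and -0.25, adjusted p of 0.00266 and 0.0394, and 0.225 and 0.274 with an estimated correlation), HLA-B having -1.19 (SE 0.23) and -2.06 (SE 0.24), and in Tau11i did not pass with GC and length offsets. Presynaptic genes fell in Tau11i (-0.24, 19 of 26 lower, adjusted p = 0.0136, and 0.274 with an estimated correlation). Neural crest markers rose in Tau441 (0.16, adjusted p = 0.00171, and 0.332), with TFAP2A at 1.33 (SE 0.24) and PAX3 at 0.97 (SE 0.24). Between Tau11i and Tau441, proliferation genes rose (0.25, 18 of 25 higher, adjusted p = 1.47e-05, and 0.299 with an estimated correlation), with BUB1B at 1.35 (SE 0.35). Of these tau libraries 3 stand apart, and without them the medians were -0.57 and -0.35 for GABAergic, 0.40 and 0.23 for neural stem, -0.15 and 0.04 for antigen presentation, -0.14 for presynaptic, 0.12 for neural crest and 0.33 for proliferation genes, in the order given. Camera passed 10, 8 and 5 of 42 lists for Tau441, Tau11i and their difference, and 0 with an estimated correlation. The counts at an unadjusted p under 0.05 were 330, 518 and 229, with DESeq2 12, 36 and 3, with the block and GC and length offsets 3 between the constructs, in the fit of all 26 libraries 11, 45 and 2, and without the libraries standing apart 98, 482 and 6, with 1 Tau441 library left. With 2 controls the self-tested fit called 16.7% (Tau441) and 12.1% (Tau11i) of genes changed by 2 (log2), so most such changes were undetectable.

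Between days, 19 of 23392 genes had a Tau11i line 6 effect that differed, 17 of them more positive at day 55, with SLITRK2 (4.25), GRIA3 (4.06), CDH13 (3.63), the neuropeptide gene ADCYAP1 (3.22) and SLC32A1 (3.14) leading and ABCB1 (-2.63) and HMGA2 (-2.14) more negative. Line 6 was in batch 3 at day 21 and in batch 1 at day 55, and line 8 likewise, so day and batch cannot be told apart here. At an unadjusted p under 0.05 there were 2484 such genes. For Tau441 line 8 the count was 0 with edgeR, 607 at an unadjusted p under 0.05, 9 with DESeq2, 7 without the count filter, 9 with GC and length offsets and 2 without the libraries standing apart. The line 6 count was 87 with DESeq2, 395 without the count filter, 70 with GC and length offsets and 26 without the libraries standing apart, 15 of these among the 19. It was 5 without either day 21 control, 6, 6 and 10 without line 6 replicates 1, 2 and 3 of day 21, 11 and 35 without line 8 replicates 1 and 3 of day 21. It was 7, 9 and 9 without the batch 1 controls, 32 and 6 without line 6 replicates 1 and 2 of day 55, and 9, 11 and 11 without the line 8 libraries of day 55.

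With time in culture the controls gained glial, progenitor, immune and matrix transcripts. From day 21 (n = 2, batch 3) to day 55 (n = 6, batches 1 and 2) astrocyte genes rose in camera's test, with a median of 3.31, 17 of 18 higher and 14 called, adjusted p = 2.72e-06, and 0.135 with an estimated correlation. The water channel AQP4 had 9.19 (SE 0.41), CLU 4.18 (SE 0.19) and S100B 4.22 (SE 0.22). Neural stem and radial glia genes rose as well (median 2.13, 17 called higher and 3 lower of 20, adjusted p = 1.54e-05, and 0.135 with an estimated correlation), with VIM at 3.91 (SE 0.20) and SOX2 at 2.23 (SE 0.17), and so did proliferation genes (1.83, 17 of 25 called higher, adjusted p = 0.000387, and 0.579). Antigen presentation (3.12, 12 of 13 called higher, adjusted p = 2.94e-06, and 0.135), with B2M at 4.94 (SE 0.22), and extracellular matrix genes (1.51, 20 called higher and 5 lower of 29, adjusted p = 0.000325, and 0.283), with SPARC at 3.74 (SE 0.18), rose in the same test. Presynaptic (-0.81, 15 of 26 called lower, adjusted p = 0.000274, and 0.335 with an estimated correlation), glutamatergic (-0.81, 8 of 14, adjusted p = 0.0287, and 0.207) and axon guidance genes (-0.71, 19 of 32, adjusted p = 0.000863, and 0.234) fell beside these rises of other cell types' markers, SYN3 having -3.47 (SE 0.18) and the cortical layer gene CUX2 -4.36 (SE 0.16). PRRX1, a mesenchymal transcription factor gene with 0 counts in both day 21 controls, was at least 396-fold higher at day 55, PSMB8 at least 52.1-fold and PECAM1 at least 20.1-fold. AJAP1 (-7.23) and ADCYAP1 (-6.62) fell too. Of 23535 genes 11663 passed, 6198 higher and 5465 lower, with 13154 at an unadjusted p under 0.05. Of 44 lists 24 passed camera and 0 with an estimated correlation. Day and batch are the same split here and cannot be told apart, and without day 21 control replicate 1 the count was 7092.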

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

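The tests of where the line 8 genes recur were chosen after the results were seen, while the interaction tests and the counts of other splits given here were planned. Effects that differed between the lines of a construct or between days are given first, as differences of log2 fold changes, and the libraries' measures come last.

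The Tau441 effect differed between line 8 and line 20 for 11 genes at day 55. It was more positive in line 8 for WNT7B (2.44), BHLHE22 (1.78), BRINP1 (1.10) and MAP3K4-AS1 (1.82), whose reads could not be separated from those of MAP3K4. It was more negative for FIBIN (-3.86), EMC10 (-3.08), MAP1LC3A (-2.70), DYNLT3 (-2.37) and SCN4B (-1.19). Of 100 splits 1, the real one, gave as many genes (highest other 8). These splits undo any Tau441 effect as well as its difference between lines, so they cannot exclude chance. Line and batch cannot be told apart. Leaving out 1 library moved the count most to 38 (batch 2 control replicate 2), 23 and 20 (line 6 replicates 1 and 3), 17 (line 25 replicate 2), 6 (batch 1 control replicates 1 and 3, batch 2 control replicate 3, line 20 replicates 1 and 3, line 8 replicates 1 and 2) and 5 (batch 2 control replicate 1).

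The Tau11i effect differed between line 6 and line 25 for 50 genes. It was more positive in line 6 for SLITRK2 (5.02), SHISA9 (3.50), ACOT2 (3.10), HSPB8 (2.85) and PCDHGB9P (7.16), a pseudogene that can share reads with its cluster. It was more negative for KLF8 (-2.00), GATA3 (-1.78), PMP2 (-1.60), COL14A1 (-1.58) and CFAP91 (-1.54). Of 100 splits 6 gave as many, so chance cannot be excluded, and the highest of the others called 3498 genes, which points to a structure of the samples. Leaving out 1 library moved the count most to 1767 and 19 (line 6 replicates 1 and 2), 27, 109 and 21 (line 25 replicates 1, 2 and 3), 29, 32 and 26 (batch 1 control replicates 1, 2 and 3) and 20 and 30 (batch 2 control replicates 1 and 3).

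The effect of Tau11i line 6 differed between day 21 and day 55 for 19 genes. It was more positive at day 55 for SLITRK2 (4.25), GRIA3 (4.06), CDH13 (3.63), ADCYAP1 (3.22) and SLC32A1 (3.14), and more negative for ABCB1 (-2.63) and HMGA2 (-2.14). Line 6 was in batch 3 at day 21 and in batch 1 at day 55, so day and batch cannot be told apart here. Without 1 library of day 21 the count was 5 (either control), 6, 6 and 10 (line 6 replicates 1, 2 and 3), 11 (line 8 replicate 1) and 35 (line 8 replicate 3). Without 1 of day 55 it was 7, 9 and 9 (control replicates 1, 2 and 3), 32 and 6 (line 6 replicates 1 and 2) and 9, 11 and 11 (line 8 replicates 1, 2 and 3).

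The 10 genes called in Tau441 line 8 at day 55, with FIBIN, EMC10 and MAP1LC3A far lower, were weighed for where else they appear. An effect of Tau441 in both lines is argued against by line 20, where the median change in the direction of line 8 was 0.10 over 8 tested genes, against 2.66 in line 8. Line 8 had the sign of day 55 at day 21 for 6 of the 6 genes tested there, with a median of 1.17 in that direction against 2.53 at day 55, but line 6 had it for 5 of the 6 with a median of 1.12 against the same 2 controls. Unusual control libraries and a difference carried by line 8 at both days both stay open as candidate explanations, but lines 6 and 8 set directly against each other argue against the controls as the whole cause for EMC10 (3.07, adjusted p = 5.49e-05) and, with the replicate number as a block, for FIBIN, MAP1LC3A and MT1G (adjusted p = 0.0297, 0.0330 and 0.00852, against 0.0801, 0.0916 and 0.0695 without it). A stronger response to more MAPT in line 8 (1.19 against 0.39 in line 20) stays open as untested. New control cultures grown beside lines 8, 20 and 6 in 1 batch would test the controls as a cause. They would not part the other 2 hypotheses, since line and MAPT level go together in lines 8 and 20.

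Dixon's ratio was computed in 15 pools of 6 libraries of a genotype at day 55, for MAPT level, total counts, genes with a count and the mitochondrial and ribosomal shares. It passed its critical value in 0 pools, where chance passes about 1 in 20, or 0.75 of 15, if a pool has 1 common level. Each pool joins 2 batches whose levels can differ, and 2 high libraries can hide each other. Line 6 replicates 2 and 3 did so with mitochondrial shares of 10.6% each, the ratio of that pool being 0.0104. The ratio therefore cannot show that no library is unusual.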

How the results depend on the processing

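The GC and length offsets, the fits without the libraries standing apart, the voom weights, the second column order for list tests and the fits with both block and offsets were chosen after seeing the data, and the other settings were planned. Of 409 counts of called genes 212 moved by over 1.5 times, and of 251 counts of passing lists 73 did. With fry 4, 0 and 1 lists passed for Tau441, Tau11i and their difference at day 55, against 11, 8 and 11 with camera. At day 21 fry passed 1, 1 and 0, against 10, 8 and 5, and for the controls of the 2 days 34, against 24. For 2684 values of lists 744 no longer passed and 25 were counted as changing sign. The antigen presentation median of Tau11i at day 21, which turned positive without the libraries standing apart, is not among these 25. For 5010 values of named genes other than MAPT, 4115 kept direction and side of the threshold, 259 passed where the reported fit did not, 635 no longer passed and 1 changed sign. For 197 values of MAPT these numbers were 172, 8, 12 and 5. The r between lines 6 and 25 of Tau11i ran from -0.0790 (without line 25 replicate 2) to 0.286 over left-out libraries and was 0.00454 without the libraries standing apart, against 0.212 with all. Where no cause is named, the cause was not tested.

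Without the count filter the calls for Tau441, Tau11i and Tau11i against Tau441 at day 55 became 254, 2294 and 3140. They became 176, 2381 and 2478 for line 8, line 6 and their difference, and 392, 198 and 384 for line 20, line 25 and their difference. The line interactions had 123 and 358, and the day interactions of line 8 and line 6 had 7 and 395. With DESeq2 the same numbers were 130, 810 and 2051, then 81, 2241 and 1636, then 365, 81 and 238, then 80 and 347, then 9 and 87, and at day 21 12, 36 and 3. With GC and length offsets they were 143, 113 and 159, then 42, 284 and 203, then 7 for line 25 and 59 for lines 25 and 20, then 64 and 113, then 9 and 70, and at day 21 1 for Tau441 and 15 for Tau11i. Without the libraries standing apart they were 208, 1 and 0, then 58, 24 and 7, then 1868, 85 and 434, then 80 for the Tau441 interaction, 2 for the line 8 day interaction, and 98, 482 and 6 at day 21. This leaves 1 library of line 6 at day 55 and 1 of line 8 at day 21. Without a batch term the day 55 counts were 0, 0 and 0, with 1 mean per group 34, 254 and 232, with all 26 libraries 4 for Tau441 and 6 for Tau11i against Tau441, and 11, 45 and 2 at day 21. The voom weights gave 115, 5 and 4.

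The 4 genes shared by Tau441 and Tau11i became 75 without the filter, 36 with DESeq2, 23 with GC and length offsets, 1 without the libraries standing apart, 0 without a batch term, 11 with 1 mean per group and 1 with all 26 libraries. Both Tau441 lines shared 12, 4 and 11 without the filter, with DESeq2 and without the libraries standing apart, and both Tau11i lines 53, 13 and 1, with 1 under GC and length offsets.

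The block moved the counts and calls given in the text for the paired comparisons and changed no other call of a gene or list named there for them. Where the numbers do not pair, the samples share only a number. Over all groups of a batch 8 of 9, 6 of 9 and 5 of 8 libraries correlated best with their own number, a hint from the data alone. With the number as a block the calls were 33, 54 and 308 at day 55, 15 for Tau11i at day 21, 21, 2609 and 1923 for line 8, line 6 and their difference, 5 for lines 25 and 20, 31 and 154 for the line interactions, 4 and 71 for the day interactions and 9 for the shared genes. With GC and length offsets in the same fit the paired counts were 1066 at day 55 and 3 at day 21 for Tau11i against Tau441, 1891 for lines 6 and 8, 78 for lines 25 and 20 and 560 for line 20.

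Leaving out 1 library at a time gave 0 to 32, 6 to 111 and 3 to 2776 calls at day 55, with the libraries named beside each comparison. In batch 1 it gave 2 to 44, 20 to 6905 and 3 to 6954, and in batch 2 0 to 1868, 0 to 85 and 0 to 434. The interactions had 5 to 38 and 19 to 1767 between lines and 5 to 35 between days for line 6. The controls of the 2 days had 7092 to 12197. Shared genes numbered 0 to 9, and genes of both lines of a construct 0 to 2 and 0 to 3. At day 21 it gave 0 calls each time.

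Signs turned for MAPT in Tau11i against Tau441 at day 55 without scaling factors (-0.0255) and at day 21 with GC and length offsets (0.0304, or 0.0338 with the block), called in none. Over left-out libraries MAPT in Tau11i against Tau441 at day 21 ran from -0.254 (without line 8 replicate 3) to 0.0232 (without line 8 replicate 2). In line 6 against line 8 it ran from -0.163 (without line 8 replicate 1) to 0.0272 (without line 8 replicate 3). MAPT ranged from 0.69 to 0.85 in Tau441, 1.07 to 1.29 in line 8 and 1.02 to 1.18 in line 6 over the left-out libraries. It was 0.39 in line 20, 0.63 in line 25 and 0.24 between these without line 25 replicate 2, where all 3 passed, and 0.70 in line 25 with GC and length offsets. Left out in turn, the libraries of batch 2 gave 0.35 to 0.46 in line 20, 0.58 to 0.68 in line 25 and 0.21 to 0.25 between them.

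Without the libraries standing apart CTSD in Tau11i against Tau441 was -0.00711. Lists turned there in Tau11i against control: postsynaptic -0.0231 with camera's direction turned, ion channels 0.0117, oxidative phosphorylation -0.11, glycolysis -0.053, axon guidance 0.0616 and ribosomal -0.028. In Tau11i against Tau441 they were ion channels 0.0328, oxidative phosphorylation -0.00884, axon guidance 0.0261 and ribosomal -0.0427. Line 6 had oxidative phosphorylation at -0.12 and ribosomal at -0.012. Line 6 against line 8 had postsynaptic at 0.0642, ion channels at 0.0387, oxidative phosphorylation at -0.0228 and axon guidance at 0.0489. Line 25 had oxidative phosphorylation at -0.0748 and ribosomal at -0.00885, and line 25 against line 20 had ribosomal at -0.11, the same without line 25 replicate 2. Without line 25 replicate 1 these 3 were highest, at 0.25, 0.54 and 0.42. At day 21 the mitochondrial median in Tau441 ran from -0.26 (without control replicate 1) to 0.0244 (without control replicate 2). Glycolysis between Tau11i and Tau441 ran from -0.41 (without line 8 replicate 3) to 0.0584 (without line 8 replicate 2).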

Other observations

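The fits without the libraries standing apart and the tests of both patterns below were chosen after the results were seen, as were the counts of other splits for Tau441 against control and those of splits that part every pair, while the remaining counts of splits were planned.

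Without the 1 Tau11i library of batch 2 that stands apart, line 25 replicate 2, Tau441 line 20 differed from its controls in 1868 genes (n = 3 against 3), against 0 by edgeR with it, where 2093 had an unadjusted p under 0.05 and DESeq2 called 365. Neuronal genes fell, 13 of 20 pan-neuronal, 18 of 26 presynaptic with 1 higher, and 11 of 29 postsynaptic, among them SYP, NRXN3, STMN2 and DLG4. Genes of dividing cells rose in 11 of 25, MKI67, TOP2A, CENPF and MCM2 among them, and 8 of 18 astrocyte genes rose, CD44, AGT and GFAP included, with 1 lower, as did 7 of 20 neural stem genes with 2 lower. Enzymes of cholesterol synthesis fell in 12 of 24, HMGCS1 and SQLE among them, and proteasome subunits in 9 of 30. By single genes PRPH, an intermediate filament of peripheral neurons, rose by 1.57 (SE 0.21), PDGFRA of glial progenitors by 1.46 (SE 0.23) and LAMA3 by 1.30 (SE 0.19). The potassium channel gene KCNJ16 fell with -2.03 (SE 0.36) and COL1A1 with -1.86 (SE 0.43). Line 25 then had 85 calls, with the lipase gene LPL at -1.18 (SE 0.21) and HSPB8 at -1.15 (SE 0.21) lower. Line 25 against line 20 had 434, with the neuronal receptor gene GRIN3A at 0.99 (SE 0.14) higher and 5 of 13 antigen presentation and 8 of 29 matrix genes lower. Beside these, 8 of 18 astrocyte genes were lower and 2 higher, 3 of 17 mesenchymal genes lower (ACTA2, PRRX1 and TAGLN), 2 of 11 oligodendrocyte lineage genes lower and 4 of 20 pan-neuronal genes higher. Over both batches, without the 3 libraries standing apart, Tau441 had 208 calls, 7 of 20 pan-neuronal genes lower (CHGB, NEFH, CHGA, STMN2, SNAP25, INA and RBFOX3) and 5 of 24 cholesterol genes lower, with IDI1, FDFT1, SQLE and INSIG1 among them. Of 18 astrocyte genes 2 were higher, and GLP1R was at -1.39 (SE 0.31) and the metallothionein MT1G at -1.59 (SE 0.31).

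At day 21, leaving out the 3 libraries standing apart left 2 controls, 2 of Tau11i line 6 and 1 of Tau441 line 8. The last is taken to vary like the others. Tau11i line 6 then had 482 calls and Tau441 line 8 had 98, against 0 each by edgeR with all libraries, where 518 and 330 had an unadjusted p under 0.05 and DESeq2 called 36 and 12. Progenitor genes rose in Tau11i, 10 of 20 neural stem genes with PAX6, VIM, SOX9, NES and NOTCH1 among them, and GABAergic genes fell, 4 of 9 in Tau11i and 3 of 9 in Tau441, with SLC32A1 and SST in both and CALB2 in Tau11i among them. Beside these, 4 of 14 mesenchymal genes were higher in Tau11i and 1 lower, with COL1A1, COL3A1, PDGFRB and TWIST1 higher, and 3 of 11 neural crest genes were higher in Tau11i and 2 of 11 in Tau441, PAX3 and TFAP2A in both. PPP2R2C, lower in both constructs at day 55, had -2.44 (SE 0.29) in Tau11i and -2.80 (SE 0.37) in Tau441. TWIST1 at 2.003 (SE 0.30) and COL1A1 at 1.69 (SE 0.28) rose and HLA-B at -2.08 (SE 0.26) and LAMP5 at -2.40 (SE 0.27) fell in Tau11i, while ROBO3 at 1.23 (SE 0.15) rose and FBLN5 at -2.44 (SE 0.34) and SEZ6L at -1.72 (SE 0.22) fell in Tau441. The lines share controls, so agreement is not independent.

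Ribosomal protein and mitochondrially encoded genes were higher in Tau11i at day 55. Trends with the GC content and length of each gene's longest annotated transcript are argued against as the whole cause, since with offsets for them the medians were 0.445 and 0.56. The transcript expressed can be a shorter one, so a trend with its length is not excluded by these offsets. An effect of Tau11i in every culture is argued against for the ribosomal genes, whose share lay above every control of its batch in 3 of 6 Tau11i libraries, and stays open for the mitochondrial genes, at 6 of 6. The libraries standing apart remain a candidate cause for both groups, with medians of -0.028 and 0.083 without the 3 libraries. What set those libraries apart was not recorded in the labels, so a difference in culture or RNA handling may lie behind them as well as a response to Tau11i that only some cultures showed, and no test here separates these.

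Pan-neuronal genes were lower in Tau441 at day 55. Trends with the GC content and length of each gene's longest annotated transcript are argued against, since with offsets the median was -0.25. A lower share of neurons was predicted to give positive medians in 4 lists of other cell types. In line 8 this was not met, as proliferation genes had the lowest median of the 4, -0.30 (camera adjusted p = 4.49e-06, and 0.523 with an estimated correlation). The other cell types need not move together, so this cannot decide whether line 8 held fewer neurons. In line 20 a lower share of neurons may account for the fall, the lowest median of the 4 lists being 0.16, in neural stem genes, with 0.39 for proliferation and 0.23 for astrocyte genes. A lower level of these transcripts within each Tau441 neuron stays open as untested.

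Regroupings of the libraries were counted for how often they gave as many calls. For Tau441 against control at day 55 1 of 100 splits, the real one, gave as many as 9 genes (highest other 2), and for Tau11i 1 of 100 gave as many as 21 (highest other 8). These counts include MAPT. The splits were drawn over both batches and not within them. Those that set a group unevenly over the batches lose power to the batch term, while the real split is even. They therefore cannot exclude chance assignment of single cultures or, with 2 lines per construct, chance differences between lines. For Tau11i against Tau441 5 of 100 gave as many as 9, so chance cannot be excluded there, and the highest other called 5849, which points to a structure of the samples that does not follow the batches. The other 4 of these splits parted 2 or 4 of the 6 pairs of equal replicate numbers, and the real one parts 6. With the number as a block the real count was 308, and of the 32 splits that part every pair 1, the real one, gave as many (highest other 16). Chance swaps within the pairs can be excluded for that count only if the numbers do pair the samples, which the labels do not state. For lists passing camera 20 of 100 splits gave as many as the 11 of Tau441 (highest other 19), 55 of 100 as many as the 8 of Tau11i (highest other 20) and 14 of 100 as many as the 11 of their difference (highest other 14), so chance cannot be excluded for the number of lists. With 3 libraries against 3 the 10 splits are too few for a share under 0.05. There the real and highest other counts were 10 and 0 for line 8 (1 split as large), 102 and 0 for line 6 (1), 41 and 5308 for line 6 against line 8 (2), 0 and 0 by edgeR for line 20 and line 25 (10 each, with unadjusted p under 0.05 in 2093 and 1420 genes, DESeq2 365 and 81), 10 and 0 for line 25 against line 20 (1), and 0 and 0 for Tau11i against Tau441 at day 21 (10, with an unadjusted p under 0.05 in 229 genes and 3 by DESeq2). The 5308 points to a structure of the samples too, and that split parts 1 of 3 pairs. It sets line 6 replicates 2 and 3, the libraries of that line that stand apart, together with line 8 replicate 3 against the rest. Of the 4 splits that part every pair, too few as well, the block gave 1923 in the real one and 0 as the highest other for line 6 against line 8 (1 as large), 5 and 0 for line 25 against line 20 (1), and 0 and 0 by edgeR at day 21 (4).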
